A study of Rattus norvegicus with 12 samples.

How the data were processed

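Small RNA was sequenced from 12 samples of SD rats, 6 labelled heart and 6 labelled serum. Per the labels' protocols, total RNA was isolated with Trizol and libraries were built with the NEBNext small RNA kit. The design text describes a coronary ligation lasting 30 minutes and a reperfusion lasting 1 week. Per the submitters' processing notes, Bowtie2 2.2.6, DESeq 1.30.0 and the genome build mRatBN7.2 were used, and no role or order of these is given. The read trimming, the miRNA annotation release, the treatment of reads that match several miRNAs and any filter on low counts are not given in the sources used here.

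The authors deposited 2 tables of results, one for heart and one called exosome, each comparing a group headed CK with a group headed M. The samples labelled serum are the only ones left for the exosome table. The meanings of CK and M are not given in the labels, and no label says which samples belong to either, so both names are kept as the headers give them. Per the file headers, each row is a miRNA with the authors' mean normalized count over all libraries (a signal in units of counts divided by size factors) and their mean for CK and for M. The authors' deposited fold is the ratio of the M mean to the CK mean, and their log2 fold change is the log2 of that ratio. A mean of 0 in a group gives an infinite fold in the deposited tables. The deposited p-value and adjusted p-value of each miRNA are the authors', and recomputing the Benjamini-Hochberg adjustment over all rows of each table gave the deposited adjusted values, with a largest difference of 6.45e-15 in the heart table and 3.12e-15 in the exosome table. No other column of sample values was present. The tables hold no standard errors, so group means are printed as the authors' means without an error. The files pair no genome positions with the miRNAs, and the gene table at hand is of another assembly (GRCr8), so no coordinates are printed. Both tables were normalized separately, and no level was tested between them.

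The counts of miRNAs past the threshold use the authors' adjusted p below 0.05, as deposited. No count model was fitted over all miRNAs, because the tables hold group means and the reads of the most abundant miRNAs could not be solved (below). Nothing in the labels says that the samples came from separate animals, so the p-values measure the spread between these samples, which may be technical.

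Reads of the separate libraries were reconstructed by arithmetic from the group means. Each deposited mean is printed to 15 significant digits and equals a sum of whole numbers times 3 fixed steps, one step per library, where a step is what 1 read in that library adds to the group mean. This shows 3 libraries per group. The 3 steps were found from the lowest means, and for every mean at which the expected number of false solutions was at most 0.01 the triple of whole reads was searched within a relative tolerance of 6e-15. Each of the searched means had exactly 1 solution. They made up 87.3% of the 574 heart values for CK and 89.2% for M, and 84.2% of the 367 exosome values for CK and 86.1% for M. The most abundant miRNAs, above means of 2913 to 4460 in the heart table and of 2643 to 4091 in the exosome table, could not be solved. On simulated means with known reads, all 351 and 358 searched heart values and all 277 and 250 searched exosome values were solved correctly. In this simulation miRNAs with a mean under 3 kept their real reads, from which the steps are found. It therefore tested the search for reads and not the finding of the steps. Size factors recomputed from the solved reads by the median of ratios lay within 2.10% of the step values in the heart table and 3.64% in the exosome table. Libraries are numbered within a group by increasing depth and cannot be matched to the labelled samples, so no value is given to a labelled sample. Their values are used as a description, in the list tests on solved miRNAs and without each library, and in 1 added check between groups. For that check, limma with a mean-dependent prior was run on log2(level + 1) of the solved miRNAs with a mean of at least 10, with Benjamini-Hochberg adjustment, for all 6 libraries, without each library and for the 10 splits of the 6 libraries. On simulated reads with a log2 shift of 2, this called 29 of 30 shifted miRNAs in each table and 1 of the others in the heart table, and with no shift it called 0. These reads were negative binomial with a dispersion of 0.1. Real exosome reads scattered more, with 64 miRNAs found in only 1 of the 6 libraries at a median of 56.5 reads. The share called in the simulation therefore does not carry over to the exosome table. Depth was estimated as the sum of the group means times the size factor of the library.

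The 15 lists of miRNAs (cell types, families and genomic clusters) and the rule for naming miRNAs were fixed at the outset. The rule took up to 8 miRNAs per direction with the largest absolute log2 fold among those past the threshold with a larger group mean of at least 10, up to 4 per list, the 5 most abundant, and up to 10 past the threshold in both tables. Where fewer than 5 miRNAs passed the adjusted threshold, as in the heart table, the rule used the raw p below 0.05. It gave 69 names for the heart table and 66 for the exosome table, of which the text names part. For each list with at least 3 members, the median log2 fold change was set against 10000 random lists of the same size matched on mean level in 10 classes, two-sided, with Benjamini-Hochberg adjustment over the lists of a table. The smallest p that this test can give is 2e-04. A miRNA with a mean of 0 in a group entered at its bound, with the mean of 0 replaced by a floor of 3 reads over the group (a mean of 1.05 in CK and 2.12 in M for heart, 1.31 and 1.30 for exosome), and at 0 where both groups lay under the floor. Floors cover counting error only, and reads made by PCR are not independent molecules. Wilson and bootstrap intervals cover spread over miRNAs, and those of arm correlations spread over hairpins. None of these intervals covers the spread between libraries. The random lists treat miRNAs as independent, and the arms of a hairpin and the members of a cluster are not, so these p-values are too small for lists of linked miRNAs. On simulated lists of 12 members with no shift, 4.5% of 200 lists in the heart table and 7% in the exosome table passed a p of 0.05. With a shift of 1 on the log2 scale, 77.5% and 76% passed. The simulated folds were independent normal values unrelated to mean level. These shares therefore do not cover linked miRNAs or folds that depend on level.

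Overlap of calls between tables was tested with Fisher's exact test, two-sided, over the 358 miRNAs in both tables. Correlations across miRNAs used 100000 permutations, and those between arms of a hairpin used 10000. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1. Other settings chosen before the data were examined were the raw p, a log2 fold of at least 1, a larger mean of at least 10, an adjusted p below 0.01, pseudocounts of 0.5, 5 and 10 on the means, unmatched random lists, 1 arm per hairpin, and a background of miRNAs with larger means. Scaling to equal totals, the solved miRNAs alone leaving out each library and limma were added after the data were seen. A named fold was labelled as moved under another setting by its spread between libraries, and for miRNAs that were not solved this spread was the median of the abundant solved ones in the same table. Near-identical mature sequences (the let-7 members, miR-26a and miR-26b, miR-199a-3p and miR-199b-3p, miR-133a and miR-133b, miR-1-3p and miR-1b, miR-29a, miR-29b and miR-29c) can share reads, so the split between members is uncertain.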

Results

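Small RNA sequencing measured miRNAs in rat heart and in serum. The design text describes ischemia and reperfusion, a model in which a coronary artery is closed and reopened. Whether CK, M or both had this operation is not given in the labels. The series title asks which miRNAs of exosomes (small vesicles that cells release) take part in healing of the heart. Each of the 2 tissues had 6 samples, and the solved means showed 3 libraries headed CK and 3 headed M in each table. The deposited tables listed 574 miRNAs for heart and 367 for the exosome samples. Estimated depth was 4059000 to 6610000 miRNA reads per heart CK library, 2253000 to 5421000 per heart M library, 1696000 to 5328000 per exosome CK library and 1855000 to 1961000 per exosome M library. The 5 most abundant miRNAs of each group made up 40.9% of the CK total and 41.0% of the M total in heart, and 46.4% and 45.3% in the exosome table.

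In heart, 2 miRNAs rose and 2 fell in M against CK at an adjusted p below 0.05 in the authors' deposited table. miR-146b-5p, which restrains innate immune signalling, rose 3.03-fold, from a mean of 3244 to 9836 normalized reads (adjusted p = 0.0220, authors' deposited table). Its reads could not be solved, so the share of single libraries in its fold is unknown. miR-221-5p, from a hairpin expressed in vessel walls, rose 3.0-fold, from 77.2 to 231 (adjusted p = 0.0483, authors' deposited table). miR-483-3p, encoded within the Igf2 gene, fell 4.25-fold, from 77.1 to 18.1 (adjusted p = 0.0220, authors' deposited table), and did not pass in limma on the solved reads (adjusted p = 0.0787). Its log2 fold was -2.30 in limma and -2.09 in the authors' deposited table. miR-6321 fell from a mean of 81.4 to 0, at least 38.3-fold lower against the floor of 3 reads, and at least 22.9-fold without CK library 3 (adjusted p = 0.0127 with all libraries, authors' deposited table). Its reconstructed reads were 36, 82 and 228 in the CK libraries and 0 in each M library. At an unadjusted p below 0.05, the authors' deposited table held 24 miRNAs higher and 20 lower in M, 44 in all where uniform p-values give 28.7 on average. At an adjusted p below 0.01 it held 0. miRNAs are not independent, and the excess over 28.7 was not tested.

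**Figure D1:**
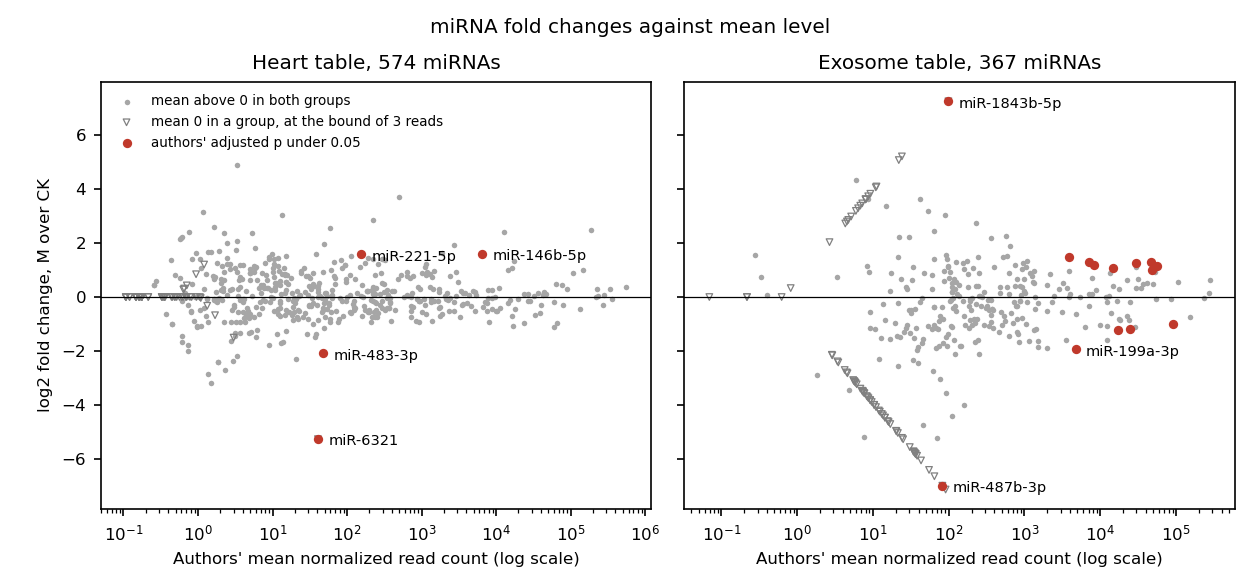
Each point is a miRNA, placed by the authors' mean normalized read count over all libraries (log scale) and its log2 fold change of M over CK, with triangles for miRNAs with a mean of 0 in a group at their bound. The 4 miRNAs past the adjusted threshold in heart and the 14 in the exosome table are red circles, and the median of exosome miRNAs with a mean of 10 to 100 lay at -1.296.

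The heart miRNA with the largest mean among those at an unadjusted p below 0.05 was miR-21-5p, a miRNA of fibroblasts and injured myocardium, with 57799.6 normalized reads in CK and 322234 in M in the authors' deposited table. That is a 5.58-fold difference (p = 0.00132, adjusted p = 0.151 in the authors' deposited table), which did not pass the adjusted threshold over all miRNAs. miR-31a-5p had the largest fold of those higher in M at this unadjusted threshold, 13.1, from 70.8 to 926 normalized reads (p = 0.0492, authors' deposited table). This value rested largely on 1 library, with reconstructed reads of 262, 2052 and 243 in M, and was 2.44 on the log2 scale without M library 2 against 3.71 with it. miR-184 (906 to 2806 normalized reads, log2 fold 1.63) and miR-147 (18.9 to 57.0, log2 fold 1.59) were higher at p = 0.00194 and p = 0.00444 in the authors' deposited table. Among those lower in M were miR-323-3p (log2 fold -2.30, and -1.60 without CK library 2), miR-196c-5p (-1.70, and -3.43 to -1.26 without each library in turn), miR-338-3p (-1.68), miR-760-3p (-1.47) and miR-346 (-1.37, and likewise -2.34 to -0.95), at unadjusted p of 0.00488 to 0.0296 in the authors' deposited table. Of 277 heart miRNAs with solved reads and a mean of at least 10, the 3 M libraries lay entirely above the 3 CK libraries for 46 and entirely below for 36. That is 29.6%, where libraries in random order give 10% on average. miRNAs that vary together can move this share far from 10%, and it was not tested.

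Muscle miRNAs fell in heart as a list. Of 11 members, 8 were lower and 3 higher in M, with a median log2 fold of -0.90 in the authors' deposited table (list adjusted p = 0.00187). The mean log2 fold of the 11 members was -0.19. None passed the adjusted threshold over all miRNAs or adjusted over the list alone, and 4 were lower at an unadjusted p below 0.05. These were miR-133a-3p, a miRNA of differentiated muscle (87890.2 to 44805 normalized reads, p = 0.0178), miR-133b-3p (1828 to 976, p = 0.0270), miR-133a-5p (1083 to 581, p = 0.0471) and miR-208a-5p, encoded in the alpha myosin heavy chain gene (99.9 to 53.3, p = 0.0457), all in the authors' deposited table. miR-1-3p, the most abundant listed muscle miRNA, had 205731 normalized reads in CK and 251909 in M (log2 fold 0.29, p = 0.734, authors' deposited table). miR-206-3p, a skeletal muscle miRNA, had 53.7 and 387 (log2 fold 2.85, p = 0.0549, authors' deposited table). miR-1b, near-identical to miR-1-3p, was not in the list, although its means were larger than those of any member. It had 365838 normalized reads in CK and 344531 in M, with a log2 fold of -0.087 in the authors' deposited table. The list was not tested with miR-1b added, so its median describes the 11 members alone. Medians of the 6 solved members with a mean of at least 10 were taken against the mean of the CK libraries. They were -0.49, -2.18 and -0.31 on the log2 scale in M libraries 1, 2 and 3. In all solved members, scarcer ones included, the list median was -0.90 with all libraries and -0.48 without M library 2, where its adjusted p was 0.0655. With 1 arm per hairpin the list had -0.43 and 0.136.

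Fibrosis- and remodelling-associated miRNAs rose in heart as a list, with 15 of 21 members higher in M and a median log2 fold of 1.11 with members at a mean of 0 at their bound (list adjusted p = 0.0014, from folds of the authors' deposited table). None passed the adjusted threshold over all miRNAs, and 1, miR-21-5p, passed adjusted over the list alone. miR-212-5p (20.4 to 79.0 normalized reads, p = 0.0299) and miR-34c-5p (168 to 443, p = 0.0384) were also higher at an unadjusted p below 0.05 in the authors' deposited table. Both arms of miR-29b, whose targets include collagen mRNAs, were lower, miR-29b-3p with 275 in CK and 145.1 in M (p = 0.0320) and miR-29b-5p with 54.9 and 21.2 (p = 0.0113) in the authors' deposited table. miR-199a-5p (4113 to 21809 normalized reads, p = 0.146) and miR-214-3p (1141 to 4328, p = 0.155), which share a primary transcript, had large folds that did not pass in the authors' deposited table. The median of the 13 solved members with a mean of at least 10 lay 0.43, 1.44 and 0.32 above the CK mean in M libraries 1, 2 and 3. In all solved members, scarcer ones included, the list median was 0.88 with all libraries. It was 0.36 without M library 2 (adjusted p = 0.0655 against random lists of reads solved from the authors' means).

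Leukocyte miRNAs rose in heart as a list, with 13 of 20 members higher and a median log2 fold of 0.56 (list adjusted p = 0.0385, from folds of the authors' deposited table). 1 member, miR-146b-5p, passed over all miRNAs, and 3 passed adjusted over the list alone, the others being miR-223-5p of myeloid cells (59.0 to 169 normalized reads) and miR-155-5p of activated immune cells (158 to 367) in the authors' deposited table. miR-142-5p had 446 and 842 normalized reads (p = 0.0239), while miR-150-5p, a miRNA of mature lymphocytes, was lower, with 10399 and 5467 (p = 0.0258, authors' deposited table). The median of the solved members with a mean of at least 10 lay 0.38, 0.46 and 0.32 above the CK mean in M libraries 1, 2 and 3. With a larger mean of at least 10 the list median was 0.33 (list adjusted p = 0.108), and with 1 arm per hairpin 0.21 (list adjusted p = 0.426). In all solved members, scarcer ones included, it was 0.79 with all libraries and 0.58 without CK library 2 (list adjusted p = 0.128).

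The Dlk1-Dio3 cluster, an imprinted locus with many miRNA genes that is active in development, had 48 of 60 members higher in heart and a median log2 fold of 0.71 with members at their bound (list adjusted p = 0.0014, from folds of the authors' deposited table). This p treats the linked members of the cluster as independent and is too small. None passed the adjusted threshold over all miRNAs or adjusted over the list alone. miR-379-5p (163 to 436 normalized reads, p = 0.0222), miR-411-5p (105 to 248, p = 0.0292) and miR-541-5p (121 to 321, p = 0.0447) were among 4 members higher at an unadjusted p below 0.05 in the authors' deposited table. The log2 fold of miR-379-5p was 1.42, and 0.99 to 2.01 without each library in turn. miR-323-3p was lower (34 to 6.91, p = 0.0274 in the authors' deposited table), with a log2 fold of -1.60 without CK library 2. The 28 solved members with a mean of at least 10 had medians of -0.45, 0.52 and -0.34 in CK libraries 1, 2 and 3 and of 0.35, 1.35 and 0.38 in M libraries 1, 2 and 3, so CK library 2 lay above 2 of the M libraries.

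**Figure D2:**
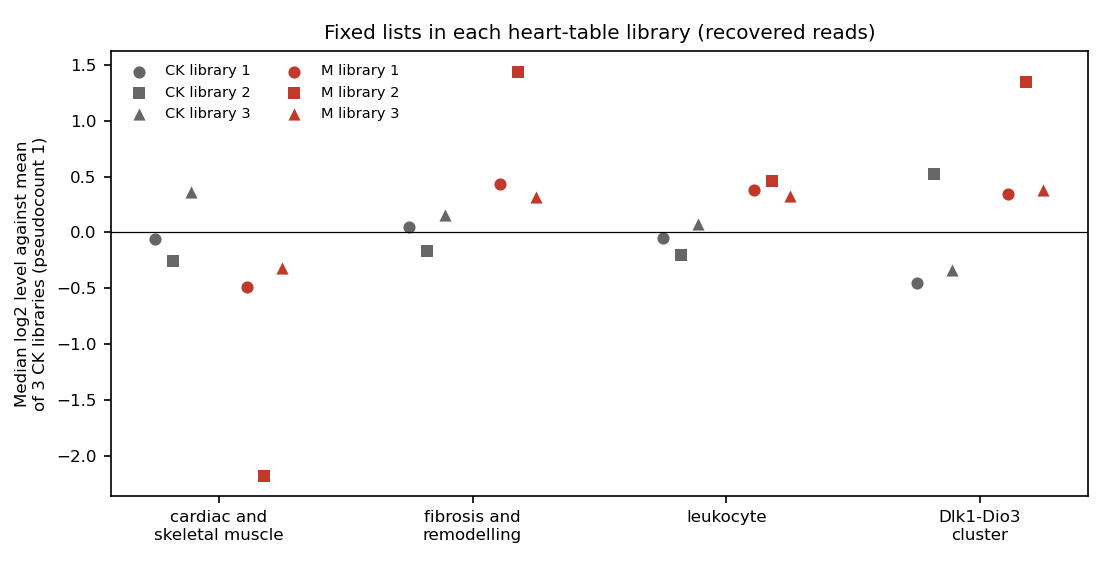
Each symbol is the median, over the solved members of a fixed list with a mean of at least 10, of the log2 level in 1 heart library against the mean of the 3 CK libraries (pseudocount 1), grey for CK and red for M. M library 2 lay farthest from 0 in each of the lists shown, at -2.18 for muscle miRNAs and 1.44 for fibrosis- and remodelling-associated miRNAs.

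Endothelial miRNAs had 6 of 7 members higher in heart, with a median log2 fold of 0.93 (list adjusted p = 0.046, from folds of the authors' deposited table). miR-221-5p passed over all miRNAs and adjusted over the list alone, while miR-126a-3p, the typical endothelial miRNA, had 308114 normalized reads in CK and 378812 in M (p = 0.581, authors' deposited table). Against random lists built from the authors' means, this list passed in 1 of 10 other settings (without M library 1), with an adjusted p of 0.0511 without M library 3 to 0.415 without M library 2 in the other 9. Its median was 0.26 without M library 2. In folds of the authors' deposited table the red cell list had a median of -0.91 and the miR-30 family of -0.45, each with a list adjusted p of 0.046, which did not pass in 9 and 10 of 10 other settings. miR-486, found in red cells and in muscle, was 81592 in CK and 37987 in M (p = 0.0313), while miR-451-5p was 2038 and 2088 (p = 0.804 in the authors' deposited table). In the miR-30 family 10 of 11 members were lower in the authors' deposited table, and 1, miR-30c-1-3p, was at an unadjusted p below 0.05 (507 to 274, p = 0.0414).

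The remaining heart lists did not pass the list test. Medians at the bound were -0.38 for smooth muscle (list adjusted p = 0.291), 0.00 for liver (1), 0.52 for neural and neuroendocrine (0.252), 0.02 for the miR-200 family (0.632), 0.17 for the miR-15 family (0.476), -0.16 for the let-7 family (0.387) and 0.17 for the miR-17~92 cluster and its paralogs (0.387), from folds of the authors' deposited table. Of these lists' members, miR-7a-5p (2024 to 3861 normalized reads, p = 0.0345) and let-7i-5p (76061 to 139853, p = 0.0346) were at an unadjusted p below 0.05 in the authors' deposited table, and 0 passed adjusted over the list alone. miR-210-3p, induced by hypoxia, had 888 and 836 normalized reads (p = 0.786, authors' deposited table), and its 2 arms were too few for a list test.

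In the exosome table, 9 miRNAs rose and 5 fell in M at an adjusted p below 0.05 in the authors' deposited table. The smallest p was that of miR-199a-3p, a miRNA of mesenchymal cells, which fell 3.82-fold from a mean of 7513 to 1967 normalized reads (adjusted p = 0.000243, authors' deposited table). miR-22-3p fell 2.28-fold (34363 to 15100.1), miR-10b-5p 2.32-fold (23999 to 10359) and miR-143-3p, a smooth muscle miRNA, 2.0-fold (122436 to 61235), with adjusted p of 0.0129, 0.0129 and 0.0291 in the authors' deposited table. miR-487b-3p of the Dlk1-Dio3 cluster fell from 165 to 0, at least 126.6-fold against the floor of 3 reads (adjusted p = 0.0265, authors' deposited table). It had reads in each of the 3 CK libraries, and did not pass in limma on the solved reads (adjusted p = 0.250). Its log2 fold in limma, on the levels plus 1, was -7.36. The bound from this floor covers counting error only. At an unadjusted p below 0.05, the authors' deposited table held 21 miRNAs higher and 30 lower, 51 in all where uniform p-values give 18.4 on average. At an adjusted p below 0.01 it held 1, miR-199a-3p. The excess over 18.4 was not tested either.

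Among those that rose were miR-26a-5p (17704 to 42097 normalized reads, 2.38-fold, adjusted p = 0.0104) and miR-26b-5p (9580.5 to 20106, 2.10-fold, adjusted p = 0.0479) in the authors' deposited table. miR-186-5p rose 2.83-fold (2038 to 5765), miR-652-3p 2.46-fold (4137 to 10171) and miR-30c-5p 2.30-fold (5047 to 11617), with adjusted p of 0.0129, 0.0265 and 0.0415 in the authors' deposited table. miR-1843b-5p rose from 0 to 198 (adjusted p = 0.0129 with all libraries, authors' deposited table), with reconstructed M reads of 313, 92 and 59. Against the floor of 3 reads this was at least 152-fold, and at least 71.4-fold without M library 1. These bounds cover counting error only, and 64 exosome miRNAs were found in only 1 of the 6 libraries, at a median of 56.5 reads. In limma on the solved reads miR-1843b-5p did not pass (adjusted p = 0.250), with a log2 fold of 7.24 on the levels plus 1. Of the 14 miRNAs past the threshold, 12 were too abundant for their reads to be solved in both groups, so that the share of single libraries in their folds is unknown. Of 249 exosome miRNAs with solved reads and a mean of at least 10, the M libraries lay entirely above the CK libraries for 14 and entirely below for 23. That is 14.9%, where libraries in random order give 10% on average, and this share was not tested.

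The let-7 family, regulators of differentiation with near-identical sequences, had 14 of 17 members higher in M in the exosome samples and a median log2 fold of 0.90 (list p = 0.0054, adjusted p = 0.0756, from folds of the authors' deposited table), which did not pass as a list. Single members did. let-7c-5p rose 2.45-fold (27158 to 66417), let-7a-5p 2.22-fold (34959 to 77467) and let-7f-5p 2.01-fold (31799.8 to 63921), with adjusted p of 0.0129, 0.0129 and 0.0265 in the authors' deposited table, and 5 members passed adjusted over the list alone, let-7g-5p and let-7d-5p being the others. With random lists not matched on mean level the list adjusted p was 0.0224. The mean log2 fold of the list, with members at their bound, was 0.23 beside the median of 0.90. Reads can be shared between let-7 members, so their folds are not separate measurements.

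Fibrosis- and remodelling-associated miRNAs had 10 of 12 members lower in M in the exosome table, with a median log2 fold of -1.76 that did not pass (list p = 0.0158, adjusted p = 0.111, from folds of the authors' deposited table). miR-199a-3p passed over all miRNAs, and it and miR-214-3p (3110.2 to 833 normalized reads, p = 0.00704) passed adjusted over the list alone in the authors' deposited table. miR-21-5p had 41079 and 58027 normalized reads (p = 0.113, authors' deposited table). Of 28 Dlk1-Dio3 members 26 were lower, with a median of -2.42 at the bound (adjusted p = 0.245, from folds of the authors' deposited table). Scarce miRNAs were lower in general, with a median of -1.296 over exosome miRNAs with a mean of 10 to 100. With unmatched random lists the adjusted p of this cluster was 0.0028.

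**Figure D3:**
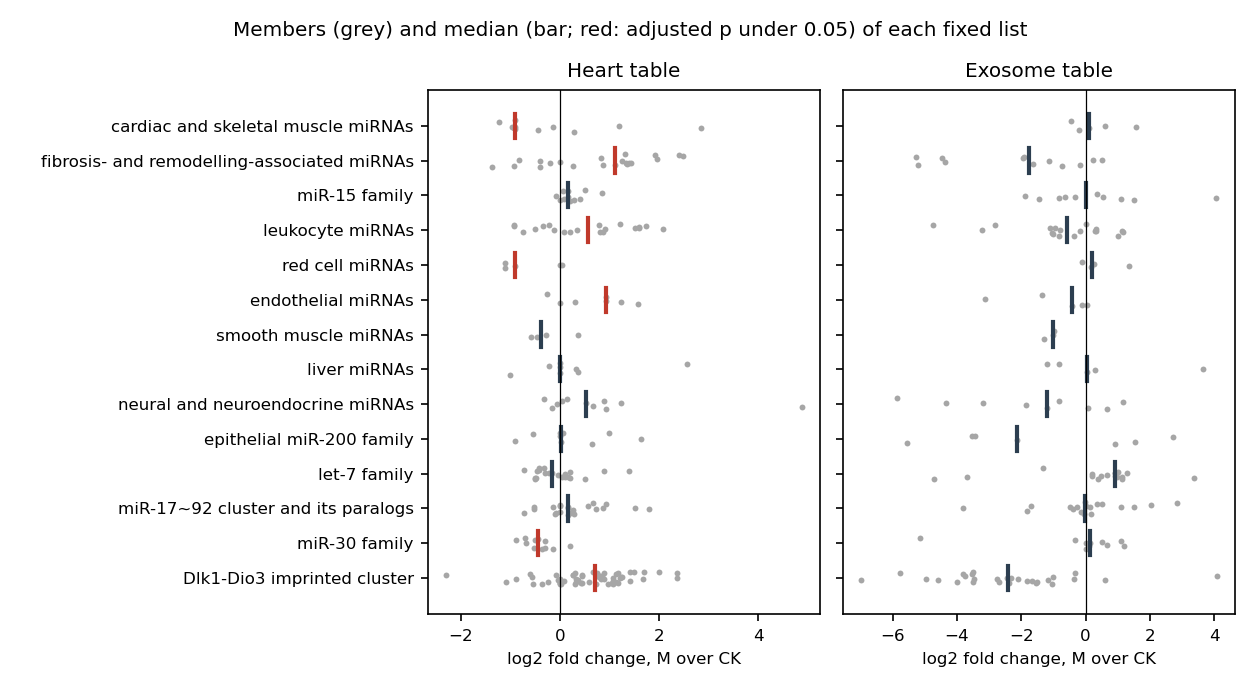
Grey points are the members of each fixed list with at least 3 members, placed by the log2 fold of M over CK in each table (at the bound where a mean was 0), and bars are list medians, red where the adjusted p of the list was below 0.05. In heart the muscle list had its median at -0.90 and the fibrosis- and remodelling-associated list at 1.11, and in the exosome table no list passed.

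Cardiac and skeletal muscle miRNAs in the exosome table had a median of 0.09 (list adjusted p = 0.663), and 0 of 5 members passed at an unadjusted p below 0.05 in the authors' deposited table. miR-1-3p had 3832 normalized reads in CK and 4091 in M (p = 0.894), miR-133a-3p 430.8 and 315 (p = 0.768), and miR-499-5p 67.8 and 103 (p = 0.820) in the authors' deposited table. The reconstructed reads of miR-1-3p in the M libraries were 1169, 6790 and 1906. Leukocyte miRNAs had a median of -0.57 (adjusted p = 0.663), with miR-146a-5p (13320.2 to 6499.7, p = 0.00231) and miR-181a-5p (8501 to 3958, p = 0.00361) lower adjusted over the list alone in the authors' deposited table. The 3 smooth muscle members had a median of -1.0 (adjusted p = 0.353, from folds of the authors' deposited table), of which miR-143-3p passed over all miRNAs. Red cell miRNAs had a median of 0.21 (adjusted p = 0.663), with miR-486 at 257951 and 287407 normalized reads (p = 0.589) and miR-144-5p at 609 and 1541 (p = 0.0155) in the authors' deposited table.

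Medians of the other exosome lists were -0.43 for endothelial (adjusted p = 0.663), 0.05 for liver (0.663), -1.19 for neural and neuroendocrine (0.663), -2.12 for the miR-200 family (0.309), 0.00 for the miR-15 family (0.663), -0.01 for the miR-17~92 cluster and its paralogs (0.663) and 0.13 for the miR-30 family (0.663), from folds of the authors' deposited table. In the miR-30 family miR-30c-5p passed over all miRNAs and adjusted over the list alone. miR-122-5p, made by hepatocytes, had 30259.5 and 16968 normalized reads (p = 0.158), miR-192-5p 1969 and 866 (p = 0.0289), and miR-375-3p of endocrine cells 2367 and 659 (p = 0.0259) in the authors' deposited table. miR-7a-5p of the neural and neuroendocrine list went the other way, with 454 and 1027 (p = 0.0195, authors' deposited table). Its libraries overlapped between groups, and its log2 fold of 1.18 was 0.66 without CK library 3 and 2.43 without CK library 1. miR-210-3p had 54.0 and 66.3 normalized reads (p = 0.836 in the authors' deposited table), and its list of 1 was not tested.

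Whether heart and exosome miRNAs moved together was asked over the 358 miRNAs in both tables. At the adjusted threshold 0 miRNAs were shared in either direction (Fisher's exact p = 1 for each, two-sided, on the authors' deposited tables). Independence gives only 0.050 shared higher and 0.028 shared lower. With 2 heart calls per direction, this test cannot tell whether calls are shared. At an unadjusted p below 0.05, 2 were higher in both, miR-7a-5p and let-7i-5p, where 1.29 were expected (Fisher's exact p = 0.376), and 2 lower in both, miR-149-5p and miR-29b-3p, where 1.3 were expected (p = 0.378, same exact test), on the authors' deposited tables. Of the 4 at that threshold in both tables, 0 had opposite directions. Across 283 miRNAs with finite folds, the correlation of the log2 folds was r = -0.04 (permutation p = 0.518) and rho = -0.07 (permutation p = 0.218), and miRNAs are not independent replicates. With 1 arm per hairpin rho was -0.15 (permutation p = 0.0276, adjusted p over 3 such correlations 0.0828). An effect past the threshold in one table and not in the other was not tested as a difference, since the tables were normalized separately and hold group means.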

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

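All tests below were chosen after the data were seen, and those on the CK library of like depth and on leaving out M library 2 before their own results were seen. In 2 of the miRNAs with solved reads and a larger mean of at least 10 in both tables, all M libraries lay above all CK libraries in heart and below them in the exosome table, where independence gives 2.89. In 0 the directions were the other way round, and independence gives 4.73 for both opposite directions together. They were miR-335, with log2 folds of 0.93 and -1.64 in the authors' deposited tables, and miR-34b-3p, with 1.31 and -5.22. The exosome value of miR-34b-3p rests on M reads of 0, 0 and 9, so that its M mean is 0 without M library 3, and its heart value was 0.59 without M library 2. For miR-335 the exosome value was -0.92 without CK library 2. The difference between tables was not tested. In 5 miRNAs the libraries were apart in the same direction, up or down, where independence gives 4.63.

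The first pattern is that few miRNAs had 1 to 4 reads in the exosome-table libraries. Their share among detected miRNAs was 1.38% to 3.57% per exosome-table library and 16.7% to 22.9% per heart-table library. Shallower sequencing is argued against by the deepest exosome-table library, with 2.49% (95% Wilson interval 1.21% to 5.05%) against 21.9% (18.3% to 25.9%) in the shallowest heart-table library. A minimum of 5 reads per miRNA and library is argued against by 33 values of 1 to 4 reads. Few molecules each read many times, in samples with little RNA, stays open as a hypothesis and may account for the 64 miRNAs found in only 1 of the 6 exosome-table libraries with a median of 56.5 reads (45 such miRNAs in heart had a median of 1), and a filter on single sequences was not tested.

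The next pattern is that scarce miRNAs were lower in M in the exosome table, with a median log2 fold of -1.296 over 111 miRNAs with a mean of 10 to 100, of which 30 were listed at 0 in M and 5 in CK. Deeper CK libraries could make more miRNAs visible, but against the CK library of about the same depth the summed level was -1.12, -0.94 and -0.96 on the log2 scale in the M libraries. That CK library had the highest sum, 7159 normalized reads against 5019 and 5988 in the others, and the mean of M lay at -0.76 against the mean of CK. Each M sum (3303, 3722 and 3680) lay below each CK sum, the shallowest CK library included, which argues against depth as the whole cause of the lower levels. Of these miRNAs 62 were detected in the CK library of like depth and 29, 47 and 60 in M, so the number detected does not separate M library 3 from it. An offset in scaling would move abundant miRNAs alike, and the median of miRNAs with a mean of at least 1000 lay 1.33 higher than that of the scarce class (95% bootstrap interval 0.96 to 1.81). Fewer molecules in the M samples, and a difference between CK and M in the serum, stay open and untested.

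The last pattern is that in heart muscle miRNAs fell while leukocyte and fibrosis- and remodelling-associated miRNAs rose. Fewer heart muscle cells in the M tissue may be involved, but miR-1-3p had a log2 fold of 0.29 beside -0.97 for miR-133a-3p, -0.43 for miR-499-5p, -0.14 for miR-208b-3p and -0.087 for miR-1b, and the spread of miR-1-3p between libraries is unknown, so this cannot be told apart from a change within muscle cells. More blood in the M tissue would raise red cell miRNAs at least as much as leukocyte miRNAs. Their median of -0.91 lay 1.47 below that of the leukocyte list (difference -1.47, 95% bootstrap interval over members -2.03 to 0.05, SD of the 5 red cell members 0.59). The difference was -1.49 to -0.79 in the 9 other settings that can move it, and the highest log2 fold of a red cell member was 0.035. However, the interval reaches 0.05, and miR-486 is also found in muscle. The 3 solved red cell members with a mean of at least 10 had medians of 0.018, -0.96 and 0.073 in M libraries 1, 2 and 3. These values lean against more blood as the whole cause but do not exclude it. Of the 3 lists, only 1 (leukocyte, 0.59, adjusted p = 0.0195 from reads solved from the authors' means) stayed past the threshold without M library 2, though all 3 kept their direction, so one deviating M library cannot be excluded as part of the pattern. The biological difference between CK and M, whose meaning the labels do not give, was not separable from these.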

How the results depend on the processing

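Settings that leave out a library, use solved miRNAs alone, use limma or scale to equal totals were chosen after seeing the data, and the other settings before. No paired analysis was possible because the tables hold group means with no sample numbers, and heart and serum lie in separately normalized tables. Count models, count filters and other size factors were left out, since reads were solved for only part of the miRNAs. Depth limits scarce miRNAs, since 3 reads over a group equal a mean of 1.05 to 2.12.

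The raw p gave 24 higher and 20 lower in heart and 21 and 30 in the exosome table, and an adjusted p below 0.01 gave 0 and 0 in heart and 0 and 1 in the exosome table, as a looser and a stricter threshold must. A log2 fold of at least 1 and a larger mean of at least 10 kept each count within 1.5 times. With limma on the solved miRNAs, which leave out 12 of the 14 exosome calls, 1 was higher and 1 lower in heart (miR-221-5p and miR-6321, not miR-483-3p), and 0 and 0 in the exosome table (33 at an unadjusted p below 0.05). Without each library the heart counts were 0 to 9 higher and 1 to 5 lower: 9 and 5 without M library 2, 4 and 2 without M library 3, 0 and 2 without M library 1 and 0 and 1 without each CK library in turn. The exosome counts stayed at 0. At an unadjusted p below 0.05 limma had 65 heart miRNAs, where the highest of the other splits of the 6 libraries had 29, and 33 and 17 in the exosome table. For heart and for exosome alike, 1 of 10 splits had as many, and 10 are too few for a share under 0.05. Shared calls at the raw p were 2 higher and 2 lower. The Spearman correlation with 1 arm per hairpin was -0.15 (p = 0.0276).

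Scaling to equal totals moved all log2 folds by -0.17 in heart and -0.13 in the exosome table, which cannot change a test against random lists beyond the draw of those lists (a new draw gave an adjusted p of 0.056 for exosome let-7, against 0.0756). It turned the medians of lists that passed under neither scaling, to -0.14 for heart miR-200 and, in the exosome table, to -0.031 for muscle, -0.12 for miR-15, -0.076 for liver and -0.000266 for miR-30. With 1 arm per hairpin the median turned to 0.043 for heart let-7, -0.49 for exosome miR-15 and -0.27 for exosome liver. With a larger mean of at least 10 it was -0.048 for exosome muscle, and in solved miRNAs 0.13 for exosome miR-17~92.

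Of the 7 heart lists past the threshold, Dlk1-Dio3 passed in all 10 settings that can change the test (0.49 to 0.86 without each library), and fibrosis and remodelling in all but 1. Each setting still treats the linked Dlk1-Dio3 members as independent, so passing in all 10 does not lift that limit. The median of CK library 2 (0.52) also lay above those of M libraries 1 and 3 (0.35 and 0.38). Calls of the other lists ended, with the direction kept, in the settings below, and the cause was not tested. With a larger mean of at least 10 the medians were 0.33 for leukocyte, -0.45 for red cell, 0.93 for endothelial and -0.45 for miR-30. With 1 arm per hairpin, where fewer miRNAs are tested, they were -0.43 for muscle, 0.21 for leukocyte, -0.91 for red cell, 0.62 for endothelial and -0.50 for miR-30. With unmatched random lists they were 0.93 for endothelial and -0.45 for miR-30. In solved miRNAs they were -0.45 for red cell, 0.93 for endothelial and -0.50 for miR-30. Without each library in turn, medians ranged from -1.16 to -0.48 for muscle and 0.36 to 1.31 for fibrosis and remodelling, both lost only without M library 2. They ranged from 0.58 to 0.97 for leukocyte, lost only without CK library 2, from -0.69 to -0.22 for red cell, 0.26 to 1.39 for endothelial and -0.76 to -0.26 for miR-30. In the exosome table unmatched random lists let let-7 (0.90) and Dlk1-Dio3 (-2.42) pass. The solved let-7 members, which leave out the abundant ones, had medians of -0.38 to 0.41 without each library.

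Mean and median differed in sign for exosome miR-30 (-0.17 and 0.13) and miR-17~92 (0.0014 and -0.0054). Pseudocounts of 0.5, 5 and 10 on both means cannot change the sign of a fold. Under them, each of the 68 heart and 64 exosome named folds that were finite stayed within its spread between libraries. This spread is an SD between single libraries and not an error of a mean, so it is a wide margin. Pseudocounts shrink the folds of scarce miRNAs most, and staying within this margin does not show that the size of those folds holds.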

Other observations

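Outside the fixed lists, and each chosen singly after its values were seen, some exosome miRNAs were lower in M at an unadjusted p below 0.05 in the authors' deposited table, and they were not tested as a group. Among them were miR-99a-5p, miR-100-5p and miR-125b-5p, with 5349.9 normalized reads in CK and 1765 in M for miR-99a-5p (p = 0.00458), 1302 and 409.6 for miR-100-5p (p = 0.0185), and 18526 and 6192 for miR-125b-5p (p = 0.00575, all in the authors' deposited table). miR-10a-5p had 23441 and 12987 (p = 0.0135), and miR-27b-3p and miR-24-3p, from hairpins of related clusters, had log2 folds of -1.06 and -0.75 (p = 0.00220 and p = 0.0119, authors' deposited table). miR-28-5p went the other way, with 198.9 and 944 normalized reads (p = 0.00489, authors' deposited table). None of these passed the adjusted threshold.

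In heart, and likewise chosen after their values were seen, miR-148a-3p (97883 to 197745 normalized reads, p = 0.0271) and the related miR-152-3p (10698 to 22339, p = 0.0419) were higher in M in the authors' deposited table. Both arms of miR-483 were lower, with log2 folds of -2.09 and -1.37, and both arms of miR-196c, with 6.01 and 0 normalized reads for miR-196c-3p (p = 0.00968, authors' deposited table). miR-122-5p, a liver miRNA, had reconstructed heart reads of 19, 14 and 32 in CK and 93, 17 and 97 in M.

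The 2 arms of a hairpin are cut from the same precursor, and their log2 folds were correlated across 163 hairpins in heart (r = 0.44, 95% interval 0.31 to 0.56, rho = 0.42, permutation p = 1e-04 for both, the smallest that 10000 permutations give). With a larger mean of at least 10 the value was r = 0.70 over 100 hairpins. Over 65 hairpins in the exosome table it was r = 0.18 (95% interval -0.07 to 0.40, permutation p = 0.157) and rho = 0.26 (permutation p = 0.0360).

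Among 277 solved heart miRNAs with a mean of at least 10, M library 2 was the one farthest from its group's median for 56.0%, M library 1 for 24.9% and M library 3 for 19.1%. In CK the shares were 21.7%, 45.8% and 32.5% for libraries 1, 2 and 3.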
